A study of Mus musculus with 12 samples.

How the data were processed

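Microglia of the hippocampus were isolated from control male BALB/c pups at postnatal day 14 and postnatal day 28 with a Percoll gradient and flow sorting, per the labels' protocols, with 6 animals per age from different litters. Per the labels' protocols, 2 ng of RNA per sample were turned into cDNA, amplified with 5 rounds of PCR and hybridised to the nCounter mouse immune panel. Copies made by PCR are not independent molecules, so counting error is a lower limit of the error of a count.

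The deposited raw table holds whole counts of barcodes per probe, which the authors did not scale, for 573 probes: 545 endogenous genes, 14 reference genes, 8 negative and 6 positive controls. A second table holds values that the authors scaled, used here as a score: per the labels, counts were scaled to positive controls and to reference genes. Each column of that score table was, within rounding, a constant multiple of the raw counts, tested on the deposited files. The text of the design gives the number of reference genes as 5 and lists 6, Alas1, Gapdh, Oaz1, Polr1b, Sdha and Tbp; all 6 were used here. It states that their coefficient of variation was under 20%. Across all samples here, that of Polr1b was 24.3% relative to the mean of the 6 genes and 29.7% relative to total counts. The other genes were under 20% on both scales. All 6 exceeded 20% on raw counts (25.0% to 33.8%) and when scaled to positive controls (24.8% to 58.5%). None of these scales therefore put all 6 under 20%. The same deposited table gives the authors' fold (a ratio of the P28 mean to the P14 mean) and a p-value per gene headed as a t-test, per the file headers. The kind of that test is not given in the sources used here, nor is the counting software. Of the authors' 336 deposited p-values, 153 were matched within 0.0001 by an equal-variance test and 49 by an unequal-variance test on the deposited values.

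Samples were grouped by the age in their titles and are named by age and the number in the title. A gene was called present, after the rule in the labels, when its raw count exceeded the mean plus 2 SD of the negative probes of its lane in at least 40% of the 12 samples. That lane threshold lay between 12.9 and 33.4 counts. Present genes were tested with edgeR 4.0.16 (R 4.3.3): glmQLFit and glmQLFTest on the raw counts, with the geometric mean of the 6 reference genes as offset, age as the only term and Benjamini-Hochberg adjustment at an FDR of 0.05. Fold changes are relative to those 6 genes. Where no sample of an age exceeded its lane threshold, the fold is given as a bound, the mean of the other age over the mean of the scaled lane thresholds of the dim age.

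In all, 25 gene lists of pathways, families and other cell types, and the panel's reference genes as 1 more list, were fixed before the data were examined, as were the test, the presence rule and the rule for the genes named. Lists with at least 3 present members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 scaled counts with a pseudocount of 1. Named genes are the 12 largest rises and 12 largest falls past the threshold, up to 4 present members of each list with the smallest adjusted p, the landmark genes Cx3cr1, Csf1r, Trem2, Tgfbr1, Itgam and Ptprc, and the 6 reference genes; 1 gene that this rule names is not reported here. Reference genes, depth and detection were compared with exact two-sided permutation tests over all arrangements of the samples, which allow no p under 0.00216. P-values of the 14 reference genes were adjusted together, as were those of 7 sample measures.

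Alternatives were DESeq2 1.42.0, limma on the authors' values or on scaled counts, other scalings, presence rules, pseudocounts and thresholds, and each sample left out in turn; others added after seeing the data are named in the closing section. On counts simulated for the 366 genes, edgeR recovered 74 of 100 genes changed 1.5-fold and 96 of 100 changed 2-fold, with 1 unchanged gene called. DESeq2 recovered 78 and 96 with 4 unchanged genes called, and limma 75 and 94 with 2. The simulated genes varied independently, with known scale factors and as many rises as falls. Errors from variation shared between genes or from the choice of scale are therefore not measured by it. Within an age, log2 scaled counts of sample pairs correlated at 0.966 to 0.995 at P14 and 0.985 to 0.995 at P28 across genes, and no pair agreed within counting noise. Gene symbols are those of the deposited table. Of the 545 genes, 535 matched a RefSeq record of GRCm38.p6 by accession, 13 of them under another current symbol, such as Emr1, now Adgre1. No genome build is named in the files, so no coordinates are given. Per-sample columns that match no sample numbered 0.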

Results

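Hippocampal microglia, the resident macrophages of the brain, were profiled in control male BALB/c mice at postnatal day 14 (P14, n = 6) and postnatal day 28 (P28, n = 6). All animals came from different litters, so the samples of a group are separate animals. The comparison asks which immune genes differ in these cells between the ages, within a study of early life stress and the maturation of microglia; stressed animals were not analysed here. RNA of the sorted cells was counted on the nCounter mouse immune panel, which captures each target with a fluorescent barcode and counts the barcodes without sequencing. The table held 545 immune genes, 14 reference genes, 8 negative-control probes and 6 positive-control probes. The raw counts of the 545 genes summed to between 356398 in P14 sample 5 and 1534665 in P28 sample 118, with means of 1005474 ± 371923 at P14 and 1313188 ± 176263 at P28 (SD, n = 6 each). Of the 545 genes, 366 were above background often enough to be tested and 179 were not. Levels are given as raw counts scaled to 6 reference genes, as mean ± SD of 6 samples per age. Log2 fold changes are P28 over P14 with their SE from edgeR's quasi-likelihood test, and adjusted p-values are Benjamini-Hochberg values over the 366 genes.

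Microglia at P28 carried more RNA of the cathepsin Ctss, of the TNF family ligand Tnfsf13b and of the chemokine Ccl6 than microglia at P14, and less RNA of the Fc receptor genes Fcer1g and Fcgrt. Ctss, which trims the invariant chain of MHC class II, rose from 41309 ± 4993 to 93755 ± 5782 scaled counts (log2 fold change 1.18 ± 0.10, adjusted p = 5.44e-07). The call of Ctss was lost when counts were scaled to positive controls alone. Cd34, a surface sialomucin best known from progenitor and endothelial cells, rose from 1198 ± 373 to 6972 ± 2568 scaled counts (2.54 ± 0.26, adjusted p = 4.02e-06). Fcer1g, the shared signalling chain of activating Fc receptors, fell from 4318 ± 499.8 to 2057 ± 77.8 scaled counts (log2 fold change -1.07 ± 0.10, adjusted p = 9.98e-07). In all, 112 of the 366 genes passed an FDR of 0.05, 61 higher and 51 lower at P28, and 158 had an unadjusted p under 0.05. The split of higher to lower calls depended on the scaling: it was 93 to 36 with the authors' own factors, 89 to 42 with all 14 reference genes, 50 to 74 without Polr1b, 51 to 96 with total counts and 8 to 127 with positive controls alone. Positive controls alone moved the median log2 fold change of all 366 genes to -0.74. Named genes that passed the main test and turned negative on that scale are therefore given with both values below. Genes that did not pass are given with the main value only, and their sign may differ there. A single value does not mean that a call held there. With positive controls alone, 17 named genes lost their call without a change of sign, among them Ctss, H2-Ob, H2-DMa, Tnf, Nfkbiz, Il7r, Socs3, Cd5 and Cd96.

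P14 samples 4 and 5 stood apart from the other P14 samples on the second principal component of the scaled log2 counts, at 5.30 and 9.16 against values from -6.83 to -3.26. That component held 25.5% of the variance, and the first, which separated the ages, held 47.9%. Without those samples, an alternative added after the data were seen, 158 genes passed, 68 higher and 90 lower at P28, and 106 of the 112 genes were called again in the same direction. Of the 366 genes, 76 had no overlap between the 6 samples of each age, a pattern that chance gives in 0.216% of splits for any gene. Of these, 75 were among the 112 calls, which were chosen on the same values. The median size of the 112 changes was 0.66 on the log2 scale, and 34 reached 2-fold, 22 higher and 12 lower. In 13 of the calls, no sample of 1 age was above its lane's background. Of these, 12 have a smallest fold over background above 1, and Gfi1, picked out after its values were seen, has none. With the 12 set to that fold and Gfi1 to no change, 29 calls reached 2-fold, 21 higher and 8 lower, and the median size was 0.63.

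The 12 largest rises covered a wide range of levels. Masp1, a serine protease of the lectin pathway of complement, was above background in 0 of 6 samples at P14 and in 6 of 6 at P28 (50.6 ± 14.4 scaled counts), at least 2.34-fold higher (adjusted p = 9.19e-07). Cybb, the catalytic chain of the phagocyte NADPH oxidase, was likewise above background in 0 of 6 samples at P14 and reached 56.4 ± 6.42 at P28, at least 2.61-fold higher. Klrd1, the CD94 chain of NK receptors, rose from 15.9 ± 6.26 to 107 ± 8.81, and Cxcl9, a chemokine induced by interferon gamma, rose from 16.9 ± 4.69 to 97.9 ± 13.2; each was above background in 2 of 6 samples at P14. Tnfsf13b, the B cell survival factor BAFF, rose from 39.6 ± 9.48 to 205 ± 30.5 (2.36 ± 0.17) and Ccl6 from 152 ± 33.2 to 603 ± 90.6 (1.98 ± 0.16). Itgax, the integrin chain CD11c, rose from 45.2 ± 17.9 to 174 ± 24.8 (1.91 ± 0.22), and Tnfrsf11a, the receptor RANK, from 335 ± 153 to 1098 ± 218 (1.70 ± 0.28). H2-Ob, a chain of the MHC class II peptide-loading modulator, rose from 300.5 ± 72.2 to 806 ± 93.8, and Pdcd1, the checkpoint receptor PD-1, from 43.2 ± 13.6 to 113 ± 25.9. Mbp, myelin basic protein, rose from 185 ± 69.2 to 468 ± 363 (1.36 ± 0.43, adjusted p = 0.0241), with 1091 scaled counts in P28 sample 118, 724 in P28 sample 119 and between 189 and 325 in the other P28 samples. That call was lost in 8 alternatives, among them leaving out P14 sample 61 or 81 or P28 sample 118 or 119 (0.91 to 1.29, adjusted p = 0.0523 to 0.0681). Among the 24 genes with the largest rises and falls, 23 had no overlap between the ages. These genes were picked on the same values, so this adds no separate support.

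The 12 largest falls, ranked by fitted fold without the bounds, held several genes that dropped under background by P28. Cxcr2, a receptor for neutrophil-attracting chemokines, was above background in 6 of 6 samples at P14 (46.7 ± 7.93) and in 0 of 6 at P28, at least 1.83-fold lower. With 0 of 6 samples above background at P28 as well, Il2rb, the beta chain of the IL-2 and IL-15 receptors, was at least 2.07-fold lower, Itgal, the integrin chain CD11a, at least 1.56-fold, Klrk1, the receptor NKG2D, at least 1.49-fold, and Cx3cl1, the neuronal ligand of the microglial receptor Cx3cr1, at least 1.06-fold. By their bounds, Itgal, Klrk1 and Cx3cl1 would rank behind genes such as Emr1, which fell by a log2 fold change of -0.72. Genes well above background fell as well. Fcgrt, the neonatal Fc receptor, fell from 5680.5 ± 557 to 2764 ± 241 (-1.04 ± 0.10, adjusted p = 1.45e-06). Fyn, a Src-family kinase, fell from 859 ± 283 to 309 ± 42.2 (-1.48 ± 0.20), and H60a, a ligand of NKG2D, from 796 ± 141 to 363 ± 83.1 (-1.13 ± 0.17). Ebi3, a chain of IL-27, fell from 288 ± 79.7 to 105 ± 6.57 (-1.45 ± 0.17), Cd79b, a signalling chain of the B cell receptor, from 422 ± 84.4 to 184 ± 46.8 (-1.20 ± 0.18) and Lck, a T cell kinase, from 98.9 ± 15.4 to 49.5 ± 8.05 (-1.01 ± 0.15).

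**Figure D1:**
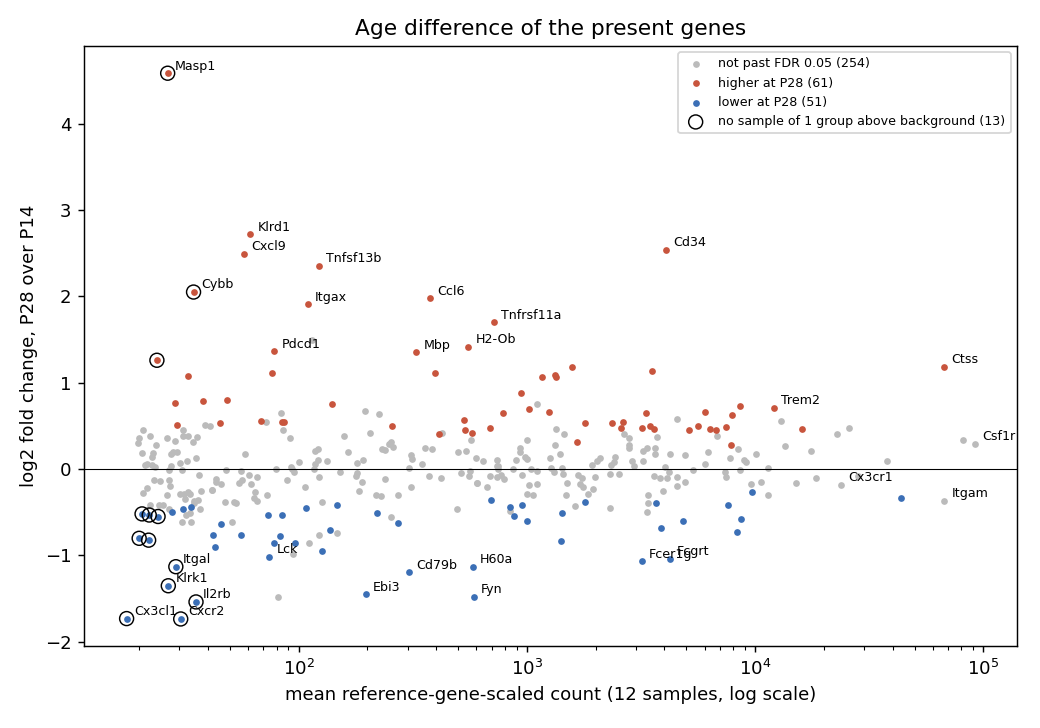
Log2 fold change of P28 over P14 (vertical axis) against the mean reference-gene-scaled count of the 12 samples (horizontal axis, log scale) for the 366 present genes, 1 point per gene. Red points are the 61 genes higher and blue points the 51 genes lower at P28, and black rings mark the 13 called genes with no sample of 1 age above background, which lie at the low end of the count axis.

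Of the genes that mark microglia, Trem2, a lipid-sensing receptor, rose from 9199 ± 1729 to 15049 ± 1261 (0.71 ± 0.13, adjusted p = 0.00069), a difference that was -0.065 with positive controls alone. Csf1r, the receptor for the survival factors of microglia, had 82169 ± 23448 scaled counts at P14 and 100769 ± 4361 at P28 and did not pass the test (0.29 ± 0.17, adjusted p = 0.212). Cx3cr1 (-0.18 ± 0.12), Tgfbr1 (0.20 ± 0.15), Itgam (-0.37 ± 0.17) and Ptprc (0.36 ± 0.17) did not pass either. Of 14 present genes of the homeostatic microglia list, 2 rose, 0 fell and 12 did not pass. Runx1, a transcription factor of myeloid cells, was the other that rose (0.47 ± 0.12, and -0.31 with positive controls alone), while Tgfbr2 (0.48 ± 0.17, adjusted p = 0.0512) and Tgfb1 (0.41 ± 0.18, adjusted p = 0.0937) did not pass. Among 8 present genes of TGF-beta signalling, Runx1 was the only 1 called, and Ski, a repressor of that pathway, had a log2 fold change of 0.56 ± 0.27. The genes of TGF-beta signalling higher and lower numbered 3 and 0 with limma on the authors' values, with all 14 reference genes and with the authors' factors, 1 and 1 without P14 samples 4 and 5, and 0 and 2 with positive controls alone.

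Of 9 present genes of MHC class II presentation, 4 rose, 0 fell and 5 did not pass. Beside Ctss and H2-Ob, these were H2-DMa, a chain of the peptide exchange factor, which rose from 249.6 ± 78.1 to 539.5 ± 54.2 (1.12 ± 0.20), and H2-Ab1, a chain of the classical class II molecule, which rose from 453 ± 32.5 to 621 ± 96.0 (0.46 ± 0.11) but was at -0.25 with positive controls alone. With positive controls alone, 0 of these 9 genes passed as higher and 2 as lower, and their median was -0.34 against -0.74 for all genes. Without P14 samples 4 and 5, 4 of the 9 passed as higher and 1 as lower. Of 10 present genes of MHC class I presentation, 3 rose and 1 fell. The genes that rose, the immunoproteasome subunits Psmb10 (0.65 ± 0.09) and Psmb9 (0.50 ± 0.11) and the proteasome ATPase Psmc2 (0.53 ± 0.12), were at -0.088, -0.21 and -0.25 with positive controls alone. B2m, the light chain of MHC class I, fell from 10594 ± 706 to 8854 ± 493 (-0.26 ± 0.08, adjusted p = 0.0263), a call lost in 12 alternatives. Among these were all 14 reference genes and leaving out P14 sample 4, 16 or 61 or P28 sample 119, 134 or 135. The left-out samples gave -0.25 to -0.24 (adjusted p = 0.0549 to 0.0627). Across the alternatives other than positive controls alone, B2m came as near to no change as -0.14, and its adjusted p reached 0.218.

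**Figure D2:**
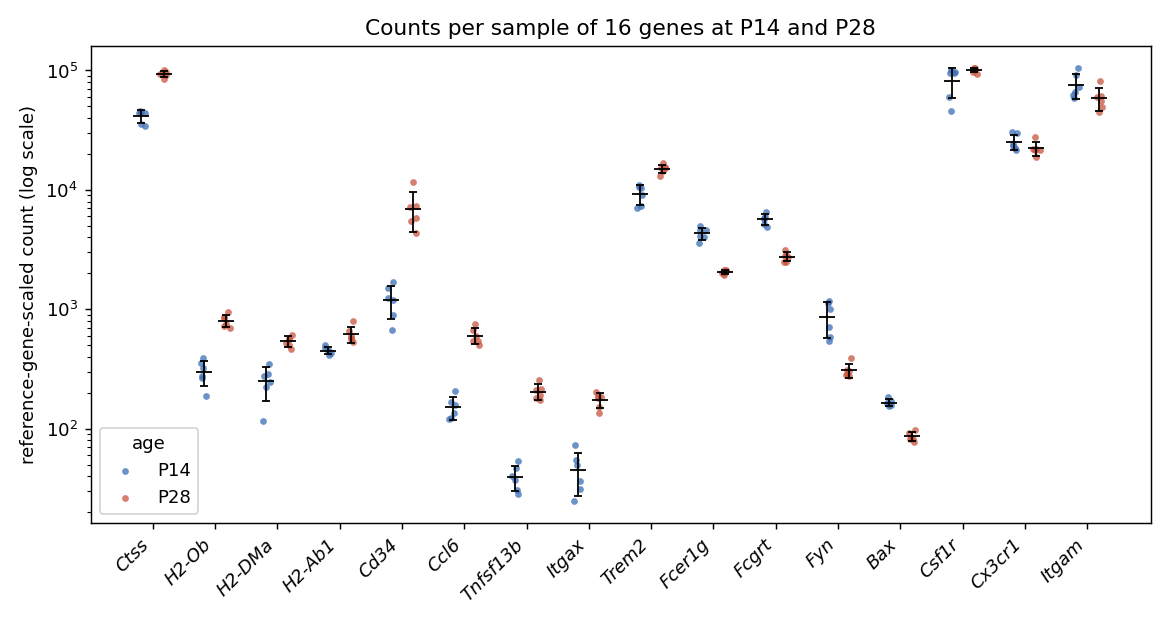
Reference-gene-scaled counts (vertical axis, log scale) of 16 genes (horizontal axis), with 1 point per sample, blue for the 6 samples at P14 and red for the 6 at P28; dashes and bars are mean ± SD. Ctss moved from 41309 to 93755 scaled counts and Fcer1g from 4318 to 2057 with no overlap between the ages, whereas Csf1r, Cx3cr1 and Itgam overlapped; H2-Ab1 and Trem2 had negative log2 fold changes when scaled to positive controls alone.

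Genes of inflammatory signalling changed in both directions. Of 24 present genes of the list of inflammatory cytokines and NF-kB, 7 rose, 4 fell and 13 did not pass, and without P14 samples 4 and 5 the counts were 5 and 7. Tnf rose from 659.8 ± 177 to 1221 ± 154 (0.88 ± 0.17), as did Nfkbiz, an atypical inhibitor of NF-kB (0.73 ± 0.18), while the NF-kB subunits Relb (-0.78 ± 0.18) and Nfkb1 (-0.68 ± 0.18) fell. The calls of Tnf and Nfkbiz were lost with positive controls alone. Of 20 present genes of Toll-like receptor signalling, 4 rose and 2 fell, against 4 and 5 without P14 samples 4 and 5. Tlr3, a sensor of double-stranded RNA (0.65 ± 0.13), Irak3 (0.56 ± 0.14) and Irak2 (0.49 ± 0.12) rose, but were at -0.15, -0.20 and -0.31 with positive controls alone, and Sigirr, a negative regulator of these receptors, fell (-0.91 ± 0.20). Of 23 present interferon response genes, Cxcl9 and Psmb9 rose, the interferon-induced GTPase Irgm1 fell (-0.44 ± 0.14, lost in 4 alternatives) and 20 did not pass, among them Irf5 (0.40 ± 0.17, adjusted p = 0.0866). Without P14 samples 4 and 5, 2 of the 23 were higher and 8 lower.

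Of 27 present chemokines and chemokine receptors, 5 rose and 3 fell, with Cxcl9 and Ccl6 among the first and Cxcr2 and Cx3cl1 among the second; without P14 samples 4 and 5 these counts were 6 and 7. Of 18 present genes of the TNF superfamily, 4 rose, including Tnfsf13b, Tnfrsf11a and Tnf, and 2 fell, including Tnfsf10, the death ligand TRAIL (-0.70 ± 0.13). Without P14 samples 4 and 5 the TNF superfamily counts were 5 and 4. Of 41 present genes of cytokine receptors and JAK-STAT signalling, 6 rose and 2 fell, against 8 and 7 without those samples. Il7r, the IL-7 receptor, rose from 2211 ± 593 to 4855 ± 433 (1.13 ± 0.17), Socs3, a feedback inhibitor of cytokine signalling, from 957 ± 428 to 2184 ± 319 (1.19 ± 0.26), and Ptpn6, the phosphatase SHP-1, by a log2 fold change of 0.45 ± 0.10 that was -0.26 with positive controls alone. On that scale the calls of Il7r and Socs3 were lost. Of 17 present phagocytic and Fc receptors, Cybb and Trem2 rose and Fcer1g and Fcgrt fell. Of 15 present complement genes, Masp1 and Itgax rose and C2 did not pass (-0.74 ± 0.32, adjusted p = 0.0924). Without P14 samples 4 and 5 the genes higher and lower numbered 3 and 3 for phagocytic and Fc receptors, 2 and 2 for complement, 3 and 2 for MHC class I and 3 and 0 for homeostatic microglia. With positive controls alone they numbered 2 and 13 for chemokines and their receptors, 1 and 6 for the TNF superfamily, 0 and 10 for cytokine receptors and JAK-STAT, 1 and 5 for phagocytic and Fc receptors and 2 and 6 for complement. On that scale they numbered 0 and 7 for inflammatory cytokines and NF-kB, 0 and 5 for Toll-like receptor signalling, 1 and 8 for interferon response, 0 and 2 for MHC class I and 0 and 3 for homeostatic microglia. With limma on the authors' values they numbered 12 and 0 for cytokine receptors and JAK-STAT, 9 and 3 for inflammatory cytokines and NF-kB, 4 and 1 for Toll-like receptor signalling, 4 and 0 for interferon response, 6 and 0 for homeostatic microglia, 5 and 0 for MHC class II and 4 and 0 for MHC class I. By the same values they numbered 4 and 1 for chemokines and their receptors, 4 and 2 for the TNF superfamily, 3 and 2 for phagocytic and Fc receptors and 1 and 1 for complement. With all 14 reference genes they numbered 12 and 3 for cytokine receptors and JAK-STAT, 9 and 4 for inflammatory cytokines and NF-kB, 5 and 0 for interferon response and 5 and 0 for homeostatic microglia.

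Of 11 present apoptosis genes, 0 rose and 1 fell. The gene was Bax, a pore-forming activator of apoptosis, which went from 166 ± 10.4 to 86.3 ± 7.35 (-0.94 ± 0.11, adjusted p = 1.46e-05); Cdkn1a (-0.39 ± 0.20), Atm (-0.39 ± 0.20) and Fadd (0.39 ± 0.21) did not pass. The autophagy and proliferation lists had 2 present genes each. Irgm1 fell and Atg16l1 did not pass (-0.16 ± 0.11) in the first, and Tfrc, the transferrin receptor, fell (-0.51 ± 0.12) and Cdkn1a did not pass in the second.

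Markers of other cells that a sort could carry were examined in the same way. Of 10 present T cell genes, Cd96 (at least 1.57-fold, above background in 0 of 6 samples at P14) and Cd5 (1.07 ± 0.20) rose and Lck and Icos (-0.42 ± 0.11) fell. The calls of Cd96 and Cd5 were lost with positive controls alone. Of 6 present B cell genes, Cd79a rose (0.76 ± 0.18, and -0.0095 with positive controls alone) and Cd79b fell, while Blnk (0.37 ± 0.18) and Tnfrsf13b (0.31 ± 0.25) did not pass. Of 7 present NK cell genes, Klrd1 rose, Klrk1 and Gzma (at least 1.10-fold) fell, and Prf1 did not pass (0.65 ± 0.31). Of 5 present dendritic cell genes, Itgax and Cd83 (0.67 ± 0.16, and -0.12 with positive controls alone) rose, while Irf4 (0.67 ± 0.27) and Batf3 (0.24 ± 0.11) did not pass. Of 4 present neutrophil genes Cxcr2 fell, and Ccr3 (-0.29 ± 0.37), Ltf (-0.13 ± 0.17) and Csf3r (0.17 ± 0.28) did not pass. Of 5 present genes of monocytes and border macrophages, Ccl24 rose (0.54 ± 0.16, and -0.14 with positive controls alone), Itgal fell, and Itga4 (0.51 ± 0.19, adjusted p = 0.0505) and Fn1 (-0.61 ± 0.23, adjusted p = 0.0512) did not pass. The only present mast cell gene, Il1rl1, did not pass (0.07 ± 0.15).

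Of 5 present genes of the list fixed for endothelial and mural cells, the endothelial cadherin Cdh5 fell (-0.63 ± 0.15) and the pericyte receptor Pdgfrb rose (0.41 ± 0.14, and -0.35 with positive controls alone). Selplg, which is not particular to vessel cells (0.64 ± 0.27), and Pecam1 (-0.43 ± 0.21) did not pass. The call of Pdgfrb was lost in 12 alternatives, among them leaving out P14 sample 4, 25 or 61 or P28 sample 118, 135, 137 or 138 (0.38 to 0.42, adjusted p = 0.0510 to 0.0715). Of 8 present genes of neurons and glia, Mbp and App (0.47 ± 0.14, and -0.31 with positive controls alone) rose, Cx3cl1 fell, and Notch1 did not pass (0.58 ± 0.21, adjusted p = 0.0512). Of 3 present erythroid and platelet genes, the blood cell transcription factor Tal1 (-0.83 ± 0.17) and Tfrc fell, and Itga2b did not pass (-0.53 ± 0.21, adjusted p = 0.0747). Counts adjusted over the list alone were the same for 19 of the 25 lists. For the others, adjusted over the list alone, they were 4 higher and 1 lower for MHC class I, 8 and 5 for inflammatory cytokines, 2 and 2 for monocytes and border macrophages, 3 and 0 for dendritic cells, 3 and 1 for neurons and glia, and 0 and 3 for erythroid and platelet cells.

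Tested as sets against the other genes with limma's camera, 0 of the 22 lists with at least 3 present members passed an FDR of 0.05, and 3 had an unadjusted p under 0.05. By camera these were MHC class II presentation (higher, median log2 fold change 0.45), dendritic cells (higher, median 0.67) and erythroid and platelet cells (lower, median -0.53), each with an adjusted p = 0.147. Without P14 samples 4 and 5 their medians were 0.23, 0.34 and -0.64 and 2 lists, the first and second of these, had an unadjusted p under 0.05 (adjusted p = 0.208 each). With an estimated correlation the adjusted p of the 3 lists were 0.885, 0.949 and 0.756, and 1 of the 22 lists had an unadjusted p under 0.05; on ranks 0 lists passed and 2 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance one way without comparing them with other genes, 4 lists passed: these 3 and neutrophils and granulocytes. By fry's test for change in either direction 20 lists passed. The median, mean and camera direction differed in sign for complement (median -0.07, mean 0.41, lower), MHC class I (median -0.03, mean 0.13, higher), interferon response (median 0.01, mean -0.0021, higher), phagocytic and Fc receptors (median -0.03, mean 0.06, lower) and monocytes and border macrophages (median 0.42, mean -0.05, lower).

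The 6 reference genes used for scaling, Alas1, Gapdh, Oaz1, Polr1b, Sdha and Tbp, were examined for a difference between the ages, since the design text states that age did not affect them. Scaled to the positive controls, 0 of the 6 passed an adjusted p of 0.05, and 2 had an unadjusted p under 0.05. The p-values came from an exact two-sided permutation test and were adjusted over the 14 reference genes of the panel. All 6 were lower at P28 on that scale, from -0.24 to -1.23, with log2 SDs of 0.48 to 0.91 at P14. That 0 passed therefore does not show that these genes were stable. Of the 6, Polr1b, a subunit of RNA polymerase I, had the lowest log2 difference on that scale (-1.23, exact p = 0.0130, adjusted p = 0.0707), and Oaz1, a regulator of polyamine synthesis, was at -0.88 (exact p = 0.0238, adjusted p = 0.0833). Relative to the mean of the 6 genes, 3 of them passed: Gapdh was higher at P28 (0.38) and Oaz1 (-0.26) and Polr1b (-0.61) were lower, each without overlap between the ages (exact p = 0.00216, the smallest possible, adjusted p = 0.00758). Gapdh was at -0.24 on the positive-control scale, 0.71 on the raw scale and 0.22 on the total-count scale, and Oaz1 and Polr1b were at 0.08 and -0.27 on the raw scale. On the raw scale 1 of the 6 passed, and on the total-count scale 2 did.

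Depth and detection were compared between the ages because both limit the low genes. Genes above background numbered 374 ± 43.8 per sample at P14 and 336.5 ± 13.3 at P28 (SD, n = 6 each; exact two-sided permutation p = 0.0758, adjusted p = 0.124). Total counts were 1.31-fold higher at P28 (exact permutation p = 0.0909, adjusted p = 0.124). The positive-control probes, synthetic targets added to each lane, gave a geometric mean of 603 ± 51.5 counts at P14 and 1167 ± 63.5 at P28, 1.94-fold higher without overlap (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00758). No run or cartridge was given in the sources used here, so a run difference and age cannot be told apart from these samples. The mean of the negative probes after reference-gene scaling was 12.1 ± 3.01 at P14 and 12.3 ± 0.716 at P28 (exact permutation p = 0.803).

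**Figure D3:**
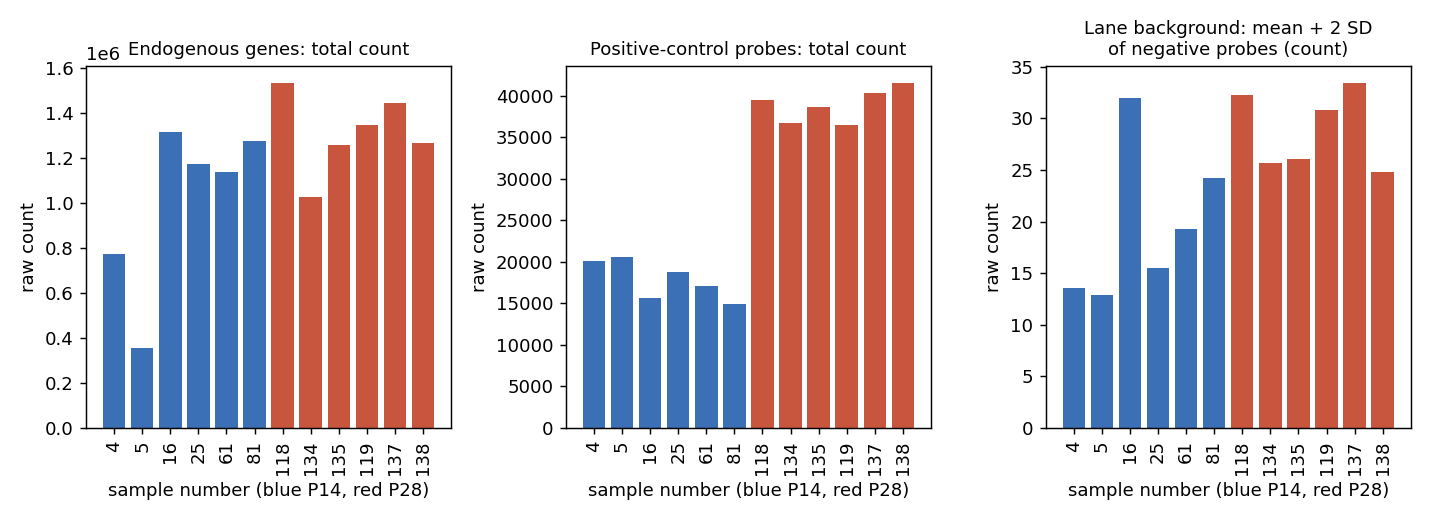
Raw counts per sample (vertical axes, bars from 0), blue for P14 and red for P28, of the endogenous genes in total, of the positive-control probes in total and of the background threshold of each lane. Every P28 lane had a higher positive-control total (36530 to 41574) than any P14 lane (14924 to 20649), while endogenous totals overlapped and P14 sample 5 had the lowest, 356398.

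The authors' deposited table lists 336 genes, 335 of which were among the 366 tested here. After Benjamini-Hochberg adjustment of the authors' deposited p-values, 108 of its genes passed 0.05, 82 with a fold above 1 and 26 below. Of these, 81 were also called here, and the authors' deposited table gave all 81 the same direction. Its 27 other calls were not called here, and 15 of the 112 calls here, among them Klrd1 and Cxcl9, lay outside the authors' deposited table. The authors' deposited table gave Ctss a fold of 2.48, Psmb10 of 1.71 and Bax of 0.57.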

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

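The tests of lymphocytes, of background and of the positive-control probes were chosen after the results they bear on were seen, as was leaving out P14 samples 4 and 5 from the calls and from the relation with depth. Within an age, 14 of 234 groups of 6 values had a sample far from the other 5 by a Dixon gap test, where chance gives about 11.7, and 6 of the 14 lay in P28 sample 138. That sample had the highest P28 scaled counts of Tgfbr2 (46345, others 21939 to 30112), Tgfb1 (42322, others 19778 to 26000), Ski (28199), Csf3r (8177), Cx3cr1 (27936) and Ctnnb1 (5556). P28 sample 137 was far above the others for Cd79b (274 scaled counts) and far below for C2 (85.0). Fyn was high in P28 sample 118 (391 scaled counts), Prf1 high in P28 sample 135 (163) and Gzma low in P28 sample 134 (6.72). At P14, Cd274 was high in sample 25 (73.8 scaled counts) and Ccl4 in sample 4 (1778). The scaled mean of the negative probes was high in P28 sample 119 (13.7).

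The age difference of 112 genes was set against 100 splits of the 12 samples into 2 groups of 6. Only the real split, 1 of 100, gave as many genes, and the highest other split gave 0, as for the 61 higher and the 51 lower genes (1 of 100 each, highest other 0). This argues against an arbitrary grouping of the samples, with 1 of 100 the smallest share these splits allow. Each other split mixed the ages in both groups, so the splits do not show how many calls arise without an age difference. For the gene lists by camera the real split gave 0, as few as any, so all 100 splits gave as many and the highest other gave 1. That outcome was fixed by the 0 and decides nothing. The lists that passed by fry were not set against splits. Low counts of P14 samples 4 and 5 do not account for the calls, since 106 of the 112 were called again in the same direction without them. What stays open is a run or reagent difference, since the positive-control probes, which carry no biology, moved relative to their geometric mean. The most concentrated probe, POS_A, moved by 0.28 on the log2 scale (exact permutation p = 0.00216, adjusted p = 0.0130). POS_C moved the other way, by -0.18 (exact permutation p = 0.00866, adjusted p = 0.0260), so the gap between these probes was wider than either shift. Each shift was smaller than the median change of 0.66 but not 0. Age, which may account for the same genes, cannot be told apart from a run or reagent difference, because every P28 lane had more positive-control counts than any P14 lane.

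Markers of T, B and NK cells changed in both directions in sorted microglia: of 23 present members, 3 of them also in another list, 9 were called, and 7 of the 9 had mean scaled counts under 100. A different share of lymphocytes at P28 would move the markers one way. Of the 9, 5 fell (Lck, Cd79b, Klrk1, Gzma and Icos) and 4 rose (Klrd1, Cd96, Cd5 and Cd79a). With positive controls alone 1 rose (Klrd1) and 5 fell, still both ways. The 4 that rose were above background in only 0 to 4 of 6 P14 samples. Among genes above background in all 12 samples, a setting added after seeing the data, 2 T cell genes and 1 B cell gene fell. There 0 T or B cell genes rose and 0 NK cell genes could be tested. The values argue against 1 common shift as the whole cause, but mainly through Klrd1. A change in a single cell type stays open. A background difference is argued against for Klrd1, Lck, Cd79b and Icos, with a mean of at least 3 times the lane threshold at 1 age, which changed by at least 42.2 scaled counts (nearest end of a 95% interval 27.6), where no negative probe's interval went beyond 12.6; for the other 5, near the floor, it stays open, since the log2 scaled negative-probe mean differed by 0.066 (95% interval -0.29 to 0.42) against a median change of 0.65 with bounds. A run or reagent difference stays open: with bounds, which can only lower dim genes, changes of at least 2-fold were found in 9 of 128 genes under 100 scaled counts and in 20 of 238 others (one-sided Fisher's exact p = 0.744), and by fitted folds in 14 of 128 (exact p = 0.269). Age-dependent expression of these genes in microglia may account for the pattern and was not tested.

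P14 samples spread along the second principal component. Per gene, the coefficient of variation across the 6 P14 samples had a median of 19.8% over 129 genes with mean counts over 1000. That was 9.75 times the Poisson value against 7.36 times at P28, but differences between animals add to both, so counting noise at low depth is not decided by it. Depth was compared with the first component of the values centred within each age, called the within-age component, not with the second principal component itself. Over the 12 samples the within-age component went with the log2 total count (Pearson r = -0.911, permutation p = 0.00012, adjusted p = 0.00055 over 5 relations; Spearman rho = -0.895, p = 0.00016, adjusted p = 0.0008; r = -0.909 without P14 sample 5 and P28 sample 134, whose totals centred by age lay farthest from the median), but it rests on P14 samples 4 and 5, without which r was -0.339 (permutation p = 0.339, adjusted p = 0.392) and rho -0.479 (p = 0.166, adjusted p = 0.207). Within P14 r was -0.938 (exact permutation p = 0.0125, adjusted p = 0.0208, n = 6) but rho was -0.829 (p = 0.0583, adjusted p = 0.0972), and within P28 r was -0.429 (exact permutation p = 0.392, n = 6) and rho -0.486 (p = 0.356), so the relation was not shown at P28. Lane depth, or an amount or quality of RNA that goes with it, may therefore account for the spread, and cannot be told apart from differences between animals at 6 samples per age. Gusb, a reference gene not used for scaling, had 615 and 499.6 scaled counts in P14 samples 4 and 5 and between 1277 and 2019 in the other P14 samples.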

How the results depend on the processing

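Across the alternatives the count of 112 genes stayed within 1.5 times except at a fold of at least 1.5 (64, 35 higher and 29 lower) and with age plus the first residual component, chosen after seeing the data (182, 107 of them higher). The causes of these moves were not tested, beyond the smaller set that a stricter threshold leaves by construction (32 lower at an FDR of 0.01). Against 61 higher and 51 lower, the split was 91 and 26 with limma on the authors' values, 51 and 96 with total counts, 8 and 127 with positive controls alone, 89 and 42 with all 14 reference genes, and 50 and 74 without Polr1b. Chosen after seeing the data, it was 93 and 36 with the authors' factors, 82 and 26 with the authors' deposited test, 68 and 90 without P14 samples 4 and 5, and 69 and 94 without these and P28 sample 138. Also chosen then, a test of only the 276 genes above background in all 12 samples gave 50 and 36. The median of all genes moved to -0.74 with positive controls alone, -0.14 with total counts, -0.12 without Polr1b, 0.13 with the authors' factors and 0.18 with limma on the authors' values. Leaving out each sample in turn gave 102 to 121 calls, 56 to 67 higher and 45 to 61 lower, with 102 to 109 of the 112 kept.

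Log2 fold changes reversed in sign with positive controls alone, by the shift of that scale, for Trem2 (-0.065), Runx1 (-0.31), H2-Ab1 (-0.25), Psmb10 (-0.088), Psmb9 (-0.21), Psmc2 (-0.25), Tlr3 (-0.15), Irak3 (-0.20), Irak2 (-0.31), Ptpn6 (-0.26), Cd79a (-0.0095), Ccl24 (-0.14), Cd83 (-0.12), Pdgfrb (-0.35), App (-0.31), Plau (-0.070), Plaur (-0.16), Itga5 (-0.35), Cd9 (-0.25), Fkbp5 (-0.24), Gpr183 (-0.13) and Il1b (-0.22). Over 3773 comparisons of a named gene with an alternative, 3516 kept their side of the threshold and, where called, their direction. Of the others, 75 lost the call, 160 gained it and 22 reversed in sign. All 22 reversals were found with positive controls alone, and these genes did not pass an FDR of 0.05 on that scale. There, 0 of the 112 calls were called in the opposite direction, and the same held in every other setting. Changes of sign in genes called neither in the main test nor in the alternative were not counted as reversals. Calls of B2m and Pdgfrb were lost in 12 of 35 settings each, other than positive controls alone, that of Mbp in 8, Cd53 in 5, Ctnnb1 and Irgm1 in 4, Gfi1 in 3, Il1a and Ccl24 in 2, and App, Ccl4, Cd9, Gzma, H2-Ab1 and Plaur in 1. On the same count, genes that did not pass gained a call: Itga4 in 15, Tgfbr2 in 14, Irf4 and Notch1 in 12, Fn1 in 11, Irf5 in 10, Itga2b in 9, Selplg in 8, C2 and Blnk in 7, Ptprc in 6, and others in 5 or fewer.

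The number of lists past the threshold, 0 with camera, was 4 with fry, 20 with fry's test for change in either direction and 0 in every other setting run. Of the 6 reference genes, 1 passed on raw counts, 2 on total counts and 3 relative to their own mean, a scale added after seeing the data, against 0 on the positive-control scale. With each sample left out, the difference in genes above background ranged from -50.1 to -24.7 (-50.1 without P14 sample 5, exact permutation p = 0.00866, -43.5 without P14 sample 16, p = 0.0498, and -24.7 without P14 sample 25, p = 0.152). The difference in total counts ranged from 177899 without P14 sample 5 to 369905 without P14 sample 16 (exact permutation p = 0.0498), and was 365313 without P28 sample 134 (p = 0.0433). No paired analysis was possible because the ages share no sample numbers. Of the 13 calls under background in all samples of 1 age, 12 have a bound above 1 and Gfi1 has none. The fitted log2 fold change of Gfi1 (-0.52 ± 0.15) is therefore not a measured size. Its call was lost in 3 settings, among them without P14 sample 81 (fitted -0.46, adjusted p = 0.0518).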

Other observations

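Of the 112 genes, 41 belonged to none of the lists, and the genes named here were chosen after their values were seen. Cd274, the ligand PD-L1 of Pdcd1, rose from 47.8 ± 13.4 to 105 ± 19.0 scaled counts (log2 fold change 1.11 ± 0.18), and Icosl, the ligand of Icos, from 847 ± 211 to 1809.8 ± 178 (1.09 ± 0.16). Ctsc, the cathepsin that activates granule proteases, rose from 753 ± 174 to 1580.4 ± 243 (1.07 ± 0.16). With positive controls alone Cd274, Icosl and Ctsc kept their sign, but only 8 of the 366 genes passed as higher on that scale. Plau, the urokinase protease, rose from 779.5 ± 111 to 1269.5 ± 79.0 (0.70 ± 0.11) and its receptor Plaur from 37.2 ± 9.39 to 53.3 ± 5.97 (0.54 ± 0.16), but these were at -0.070 and -0.16 with positive controls alone. Emr1, the macrophage marker F4/80, fell from 10361 ± 611 to 6275 ± 345 (-0.72 ± 0.08, adjusted p = 1.04e-05).

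The integrin chain Itgb1 fell from 10327 ± 2406 to 6928 ± 499 (-0.58 ± 0.15), as did beta-catenin, Ctnnb1 (-0.60 ± 0.18, a call lost in 4 alternatives), and the tetraspanin Cd53 (-0.51 ± 0.15, lost in 5), both lost without P14 samples 4 and 5 (-0.37, adjusted p = 0.0644, and -0.32, adjusted p = 0.0543), while the integrin chain Itga5 (0.40 ± 0.10) and the tetraspanin Cd9 (0.54 ± 0.16) rose but were at -0.35 and -0.25 with positive controls alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 2668 ± 241 to 3723 ± 276 (0.48 ± 0.09), and Gpr183, an oxysterol receptor, from 6232 ± 748 to 9666 ± 1285 (0.63 ± 0.11); they were at -0.24 and -0.13 with positive controls alone. Within the inflammatory list, Il1a rose from 4665 ± 1370.5 to 7356 ± 550.0 (0.66 ± 0.17, a call lost with TMM, total counts and positive controls alone) and the chemokine Ccl4 from 869.5 ± 478 to 1813 ± 706 (1.06 ± 0.32, and 0.85 without P28 sample 118, adjusted p = 0.0528), and Il1b from 69.9 ± 13.4 to 103 ± 13.7 (0.54 ± 0.15), the last at -0.22 with positive controls alone.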
